A study of Mus musculus with 10 samples.

How the data were processed

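RNA was measured on 10 Affymetrix arrays, which are 5 samples hybridised to each of 2 mouse array types, called array A and array B here. All samples carried the genotype Ink4c-/-;p53-/-, per the labels. GNP stands for purified granule neuron precursors from the cerebellum of pups 6 days old (3 biological replicates). The N-myc-labelled sample and the cyclin D1-labelled sample (1 each) are brain samples that received such precursors after infection with a retrovirus expressing N-myc or cyclin D1. Both are called infected samples, and the series' design text names 2 states. Whether arrays A and B of a label carried the same RNA extract is not stated in the sources used here.

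The deposited values are MAS5 signal intensity values on a linear scale, 1 per probe set and sample, which the authors made with MAS5, per the labels' processing notes. The MAS5 version and detection calls are not given in the sources used here. The 2% trimmed mean of every column was 500, the mark of global scaling by the authors, so no further scaling was applied. Total RNA was extracted with Trizol and made into biotin-labelled cRNA, per the labels' protocols. Array data carry no read depth, and the number of arrays limits the precision.

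Values were analysed as log2(signal + 32), so a fold change is on that scale and understates the change of dim probe sets. Where every sample of a state lay under the median signal of its array, a probe set is called dim there, and the size of its log2 difference depends on the offset. Affymetrix control probe sets were left out. A probe set was kept when its signal was at or above the median of its own array in at least 2 of the 5 samples, which kept 12565 of 22626 probe sets on array A and 12741 of 22511 on array B. The 100 non-control probe sets present on both array types were taken from array A, a choice that the plan made before the data were examined did not mention. On these 100, 4 of the 5 samples matched best across array types with their own label. The exception was GNP replicate 1, whose array A profile had r = 0.275 with its own array B profile and 0.321 with that of another GNP replicate.

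Gene names came from the platform's annotation, checked by Entrez identifier against a RefSeq gene table of assembly GRCm38.p6, with 20351 probe sets matched on array A and 14486 on array B and 0 renamed. On array A, 20380 probe sets had 1 gene name, 691 had several and 1555 had none. On array B these numbers were 14661, 245 and 7605. Probe sets with several names were left unnamed. The same table gave each gene's chromosome and order, and none of its coordinates is printed because the files name no build. One probe set stood for each of 12070 genes, from array A where possible and then the one with the highest mean log2 value. Where several probe sets of a target gene are described, they are told apart by their signal in GNPs.

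Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), separately for each array type because the types were normalized separately, with Benjamini-Hochberg adjustment over both together and a threshold of 0.05. The state comparison set the 2 infected samples against the 3 GNP replicates. The N-myc and cyclin D1 comparisons set 1 sample against 3 in a fit with 3 groups, where the lone sample is assumed to vary like the GNP replicates. N-myc against cyclin D1 is 1 sample against 1, so it has no test. A gene was counted there when the log2 difference was at least 2 in size and larger than the range of the GNP replicates. Both single-sample comparisons share the GNP replicates, so their agreement was set beside 100 simulations of unchanged groups.

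The 21 gene lists were fixed before the data were examined. They were tested with limma's camera in the state comparison, at a preset inter-gene correlation of 0.01, with an estimated correlation as an alternative. List and chromosome medians of each infected sample were ranked among 10000 random gene lists of equal size, matched on mean expression in 20 bins. Named genes followed a rule fixed beforehand. It took all probe sets of Mycn, Ccnd1, Cdkn2c and Trp53, and up to 12 rises and 12 falls past the threshold whose infected samples both lay beyond all GNP replicates. It also took up to 4 members per list with the smallest p, and 8 genes per direction for N-myc against cyclin D1. Clone and predicted names were left out of the rises, falls and the last set. Trp53 is not analysed here, since no probe set carries that name in the annotation used.

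The procedure was tested on simulated data with 200 of 25306 probe sets changed in each of 10 runs. In the state comparison, with noise of the size that fit estimated, 0.4% of changes of log2 1 were recovered, 29.0% of log2 2, 72.6% of log2 3 and 93.6% of log2 5. In the N-myc comparison, with noise as its own 3-group fit estimated it, the shares were 0%, 3.8%, 37.4% and 79.8%. With the larger noise of the state fit they were 0.2%, 1.0%, 16.8% and 71.0%. Of all calls in these simulations, 5.51% were false in the state comparison, and 4.42% and 6.51% in the N-myc comparison. In the list test, over 12070 genes, a mitosis list shifted by 1 in log2 was found in 10 of 10 runs, and 0 of 200 tests of unshifted lists passed. Genes were drawn independently of each other there, so these runs do not show how often lists of correlated genes pass falsely.

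The alternatives were an offset of 1 or 100, quantile normalization, median centring, no filter, a stricter filter at the 75th percentile of mean log2, an intensity trend, both array types in 1 fit, adjustment within each array type, and leaving out each sample. Named genes were also read with their other probe sets. The lists were also run with the mean over a gene's probe sets, and N-myc against cyclin D1 with a difference of at least 1. Leaving out each infected sample was added for the lists after seeing the data.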

Results

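Expression was compared between purified granule neuron precursors (GNPs), the dividing cells of the young cerebellum that give rise to granule neurons, and 2 brain samples that had received such cells after retroviral infection. The series concerns mouse medulloblastoma, a tumour of the cerebellum, and the making of tumours from these precursors. Every sample lacked Ink4c (Cdkn2c), an inhibitor of cyclin-dependent kinases, and the tumour suppressor p53. GNPs were measured in 3 biological replicates, and the N-myc and the cyclin D1 infected samples once each, all on array types A and B. The GNP replicates correlated with each other at r of 0.923 to 0.950 on array A and 0.80 to 0.846 on array B, across probe sets. GNPs correlated with infected samples at 0.807 to 0.820 on array A and 0.705 to 0.778 on array B. The infected samples correlated with each other at 0.824 and 0.757, and on array B the cyclin D1-labelled sample correlated better with GNP replicates 1 (0.778) and 2 (0.766) than with the N-myc-labelled sample. The ratio of the 3' to the 5' actin control on array A, a sign of RNA integrity, was 1.28 to 1.51 in the infected samples and 1.06 to 1.36 in GNPs. The same ratio of the GAPDH control on array B was 0.974 to 0.981 in the infected samples and 0.761 to 0.929 in GNPs, so a difference in RNA integrity is not separated from the states.

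The genes that the retroviruses carry were examined first, because they check the labels. Mycn, which encodes N-myc, was read by 3 probe sets that differed. The dimmest in GNPs had a signal of 97.3 ± 43.4 (SD, n = 3) there, 28639 in the N-myc-labelled sample and 31554 in the cyclin D1-labelled sample (adjusted p = 0.00112 in the state comparison). On array A, this probe set and 3 without a gene name went from under 300 in every GNP replicate to over 4000 in both infected samples. A second Mycn probe set, drawn from the same GenBank record, read 316 ± 57.4 (SD, n = 3) in GNPs, 1020 in the N-myc-labelled sample and 269.9 in the cyclin D1-labelled sample. The Mycn probe set brightest in GNPs read 2294 ± 369 (SD, n = 3), 1735 and 2292. The GNP values of the dimmest probe set lie under the median signal of their arrays of type A, 232.6 to 261.3, so the size of the difference depends on the offset and no fold is given. One Mycn probe set was as high in the cyclin D1-labelled as in the N-myc-labelled sample while the other 2 were not raised there. This leaves the cyclin D1 label in doubt without deciding it, and the infected samples are named by their labels throughout.

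Ccnd1, which encodes cyclin D1, also had 3 probe sets. The dimmest in GNPs read 1524 ± 156 (SD, n = 3) there, 4994 in the N-myc-labelled sample and 5730 in the cyclin D1-labelled sample, a rise of 1.79 in log2 (SE 0.213, adjusted p = 0.0446). That call held in 6 of 13 alternatives and was lost without any 1 of the GNP replicates. The next read 2706 ± 319 (SD, n = 3), 9383 and 3523, and the brightest read 3474 ± 257 (SD, n = 3), 6635 and 2766. In the state comparison neither of these passed, and in the N-myc comparison the first of them did (log2 1.79, adjusted p = 0.0495). In the cyclin D1-labelled sample these last readings were 1.30 and 0.796 times the GNP mean, and lower than in the N-myc-labelled sample. Which part of Ccnd1 the vector carries is not given in the sources used here, so they do not settle the label. Cdkn2c read 289 ± 254 (SD, n = 3) in GNPs, and 250.1 and 642.6 in the infected samples. All samples carried the knockout, and whether the probe set lies in the deleted part is not given in the sources used here, so that value checks no label.

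**Figure D1:**
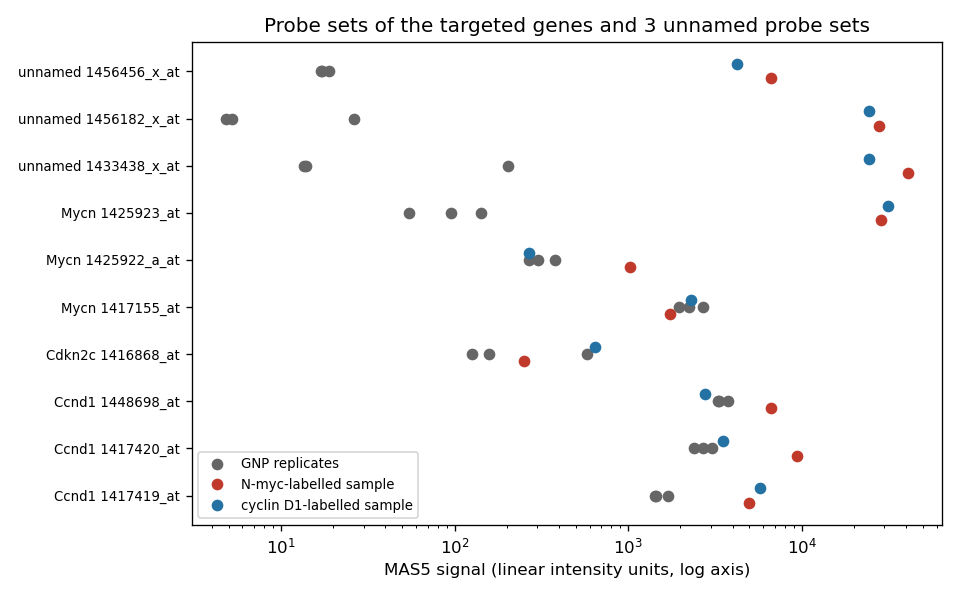
MAS5 signal on a log axis for each sample, for the probe sets of Mycn, Ccnd1 and Cdkn2c and for 3 probe sets without a gene name. Points are single samples, with GNP replicates in grey. The Mycn probe set dimmest in GNPs stands at 28639 and 31554 in the infected samples against a GNP mean of 97.3.

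The state comparison asks how the infected samples differ from the precursors. For 17 of the 24 genes named here all samples of a state read under the median of their arrays, so their signals are given and no size in log2. Of genes given in log2 further on, Eng, S100a6, Cntn2, Cd74 and Sp5 were dim in the same way, as were the called Foxm1 probe set and, in the N-myc-labelled sample, Gabrb1 and the second Cnp probe set called, so these sizes depend on the offset. Among the falls, Skor1, a transcriptional corepressor, fell from a signal of 5047 ± 1100 (SD, n = 3) to 66.5 in the N-myc-labelled and 124.5 in the cyclin D1-labelled sample (adjusted p = 0.0133). Gdf10, a ligand of the TGF-beta family, fell from 2459 ± 1343 (SD, n = 3) to 86.9 and 134.6 (adjusted p = 0.0432), and the transcription factor gene Tfap2b from 2227 ± 502 (SD, n = 3) to 120.4 and 206.1 (adjusted p = 0.0358). Mfap4, a gene of matrix microfibrils, fell from 1394 ± 159 (SD, n = 3) to 26.5 and 25.7 (adjusted p = 0.00173). Tnc, which encodes tenascin C, fell from 1211 ± 435 (SD, n = 3) to 113.3 and 76.2 (adjusted p = 0.0358).

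Among the rises, Sox18, a transcription factor of endothelial cells, rose from 369 ± 57.6 (SD, n = 3) to 3980 in the N-myc-labelled and 1853 in the cyclin D1-labelled sample. Its rise was 2.79 in log2 (SE 0.353, adjusted p = 0.04999, just under the threshold). Cavin2, a protein of caveolae, rose by 2.76 (SE 0.234, adjusted p = 0.0261) with all 3 of its probe sets past the threshold. Plxnd1, a semaphorin receptor, rose from 53.5 ± 9.96 (SD, n = 3) to 663.5 and 659.4 (adjusted p = 0.0133), and the matrix protein gene Mgp from 17.3 ± 7.91 (SD, n = 3) to 614.4 and 389 (adjusted p = 0.0225). The chemokine gene Ccl5 rose from 30.3 ± 5.63 (SD, n = 3) to 414 and 916.6 (adjusted p = 0.0358). The interferon-induced Ifitm3 rose by 2.75 (SE 0.336, adjusted p = 0.0446) and the metallothionein gene Mt2 by 2.50 (SE 0.25, adjusted p = 0.0358).

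The other rises named by the rule were Car2 (log2 2.49) and, with a GNP mean of 8.70 to 66.2, Snhg11, Bhlhe40, Cnn2 and Cflar. The other named falls were Selenom (-2.40), Fxyd6 (-2.20) and, with infected samples at 12 to 138.1, Rps4l, Serf1, Dbx1, Chchd7 and Pde9a. For Serf1, 3 of 4 probe sets did not pass, and for Chchd7 and Snhg11 1 of 2 did not. Mgp, Plxnd1, Bhlhe40 and Rps4l lie on chromosome 6 and Serf1 on chromosome 13, the chromosomes whose genes shifted as a group. The shift of chromosome 6 was upward, yet 3 genes called higher and 4 called lower lie there, Rps4l among the latter. Chromosome 13 shifted downward and held 0 genes called higher and 2 called lower.

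**Figure D2:**
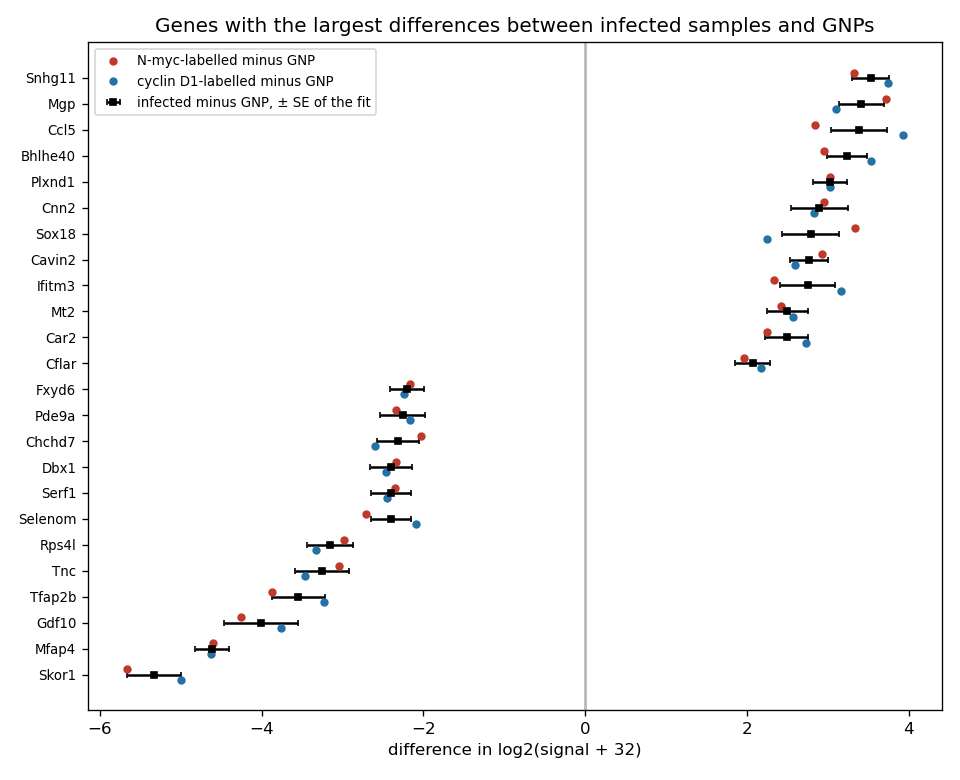
Difference in log2(signal + 32) from GNPs for the 12 rises and 12 falls that the rule named, with 1 probe set standing for each gene. For 17 of them the size, and with it the order, depends on the offset of 32. The Mycn probe set dimmest in GNPs and probe sets without a gene name, 3 of which were far above GNPs, are not ranked. Squares with bars give the state comparison ± SE, and coloured points give each infected sample minus the GNP mean. Sox18 lies at 2.79 and Selenom at -2.40.

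In total 78 of 25306 probe sets passed the test, 41 higher and 37 lower, with both infected samples beyond all GNP replicates in each of the 78. That split turned under some alternatives, with 37 higher and 69 lower under median centring, 140 and 303 under the stricter filter and 187 and 312 with an intensity trend. At an unadjusted p under the same limit there were 3950. The count was 4 without the filter, 36 with both array types in 1 fit, 37 with an offset of 1, 162 with an offset of 100, 443 with the stricter filter and 499 with an intensity trend, and of the 24 genes named Mfap4 alone kept its call without the filter or without any 1 GNP replicate. Without GNP replicate 1, 2 or 3 the count was 4, 4 and 5, without the N-myc-labelled sample 273 (93 higher, 180 lower), and without the cyclin D1-labelled sample, whose label is in doubt, 448 (55 higher, 393 lower).

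Gene lists fixed beforehand showed which groups of genes differed together. Matrix and meningeal genes were higher, with all 15 measured members above GNPs in value and 14 of them above every GNP replicate in both infected samples (median log2 1.53, camera adjusted p = 1.61e-12, and adjusted p = 0.276 with an estimated correlation). Examples are Mgp, which passed singly, Lgals1 (log2 1.62), S100a6 (2.57) and Sparc (2.66). Of 17 endothelial and mural markers 9 gave a value, and all 9 were higher (median 0.99, adjusted p = 2.33e-05, and adjusted p = 0.276 with an estimated correlation). Among them were Eng (2.26) and Rgs5 (1.95), with 0 past the test singly. Adjusted over the list alone, 14 matrix and 6 endothelial genes were higher.

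Of 20 interferon and antigen presentation genes 11 gave a value, and all 11 were higher (median 2.53, adjusted p = 1.41e-06, and adjusted p = 0.352 with an estimated correlation). Of these, 1 gene, Ifitm3, rose past the test over all probe sets, and 7 rose adjusted over the list alone. Their median was 1.08 in the N-myc-labelled and 3.56 in the cyclin D1-labelled sample. Without the latter the list's median was 1.42, over a changed set, since the probe sets standing for H2-Aa and Cd74 then failed the filter. H2-D1 (log2 3.13) and B2m (2.53), which encode parts of MHC class I, did not pass. Microglia and macrophage markers had 15 of 16 members higher in value (median 0.67, adjusted p = 0.00459, and adjusted p = 0.607 with an estimated correlation), with 0 passing singly or adjusted over the list alone. Their median was -0.03 in the N-myc-labelled and 1.30 in the cyclin D1-labelled sample, and the adjusted p was 0.562 without the latter. Hypoxia and glycolysis genes had 10 of 13 higher in value (median 0.48, adjusted p = 0.00724, and adjusted p = 0.31 with an estimated correlation), with 2 higher adjusted over the list alone. In that list Aldoa, a glycolytic enzyme gene, rose by 1.91 (SE 0.224, adjusted p = 0.0446, lost without any 1 GNP replicate), and Hk2 had a value of 1.35. The hypoxia list had an adjusted p of 0.119 without the N-myc-labelled sample.

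Lists of dividing precursors were lower. Mitosis genes had 23 of 25 members lower in value (median -0.59, camera adjusted p = 1.01e-06, and adjusted p = 0.31 with an estimated correlation), including Nusap1 (-1.04), Mki67 (-0.82) and Ccnb2 (-0.81). DNA replication genes had 17 of 23 lower in value (median -0.26, adjusted p = 0.0346, and adjusted p = 0.607 with an estimated correlation), such as E2f1 (-0.93) and Tk1 (-0.83). Their median was -0.45 in the cyclin D1-labelled and -0.003 in the N-myc-labelled sample. The DNA replication call was lost in 5 of 12 alternatives, where the adjusted p over all 12 ran from 0.00529 to 0.691, the highest being without the cyclin D1-labelled sample. In both lists 0 members passed singly or adjusted over the list alone with the probe set that stood for the gene, while another Foxm1 probe set fell (-2.11, adjusted p = 0.0399) and the remaining ones read -0.17 and 0.44.

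Lists of granule cell identity and of neural progenitors were lower too. Granule neuron differentiation genes had 14 of 22 members lower in value (median -0.57, adjusted p = 0.00448, and adjusted p = 0.607 with an estimated correlation), among them Cntn2 (-2.77), Tubb3 (-1.22) and Dcx (-1.16). The other 8 were higher in value, such as Snap25 (1.33, and 2.40 in the cyclin D1-labelled sample). Granule precursor transcription factors had 10 of 13 lower in value (median -0.43, adjusted p = 0.0185, and adjusted p = 0.429 with an estimated correlation). Pax6 (-1.36) and Zic1 (-0.95) were lower in value while Atoh1, which specifies granule precursors, was higher (1.12). Adjusted over the list alone, 7 differentiation genes and 4 transcription factor genes fell and 1 transcription factor gene rose. Neural stem and progenitor genes had 9 of 9 lower in value (median -0.38, adjusted p = 0.00731, and adjusted p = 0.31 with an estimated correlation), with 0 passing adjusted over the list alone. Of these 9, only 3 lay below every GNP replicate in both infected samples. Another probe set of Msi1, a member of the list, read 2.69 in the state comparison (adjusted p = 0.0516). Without the N-myc-labelled sample these lists had adjusted p of 0.173 (median -0.36), 0.126 and 0.0957. Without the cyclin D1-labelled sample the transcription factor and progenitor medians were -0.81 and -0.61. The progenitor list also lost its call with the mean over a gene's probe sets (0.107) and with the stricter filter (0.0553).

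The other 11 lists did not pass. Their camera adjusted p was 0.0867 for astrocyte markers and for immediate early genes, 0.0744 for lymphocyte markers, 0.543 for Myc-family targets, 0.601 for Wnt targets, 0.678 for p53 targets and for oligodendrocyte markers, 0.792 for the SHH, Notch and erythroid lists and 0.977 for Purkinje and interneuron markers. For the SHH pathway list the median was -0.10 while the mean was 0.07, and the test pointed up. The Notch and p53 lists likewise had medians of -0.03 and -0.001 with means of 0.10 and 0.15, and tests that pointed up. Astrocyte markers went both ways, and adjusted over the list alone 8 rose, such as Clu (2.65), and 5 fell, such as Aqp4 (-1.40). Adjusted over the list alone, 2 oligodendrocyte genes rose and 2 fell, 1 Wnt target and 1 Purkinje or interneuron gene rose and 1 of each fell, and 1 SHH and 1 lymphocyte gene rose. Of 268 measured list genes, 3 passed singly over all probe sets with the probe set that stood for the gene, and Mycn, Ccnd1, Ccnd2 and Foxm1 passed with another.

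**Figure D3:**
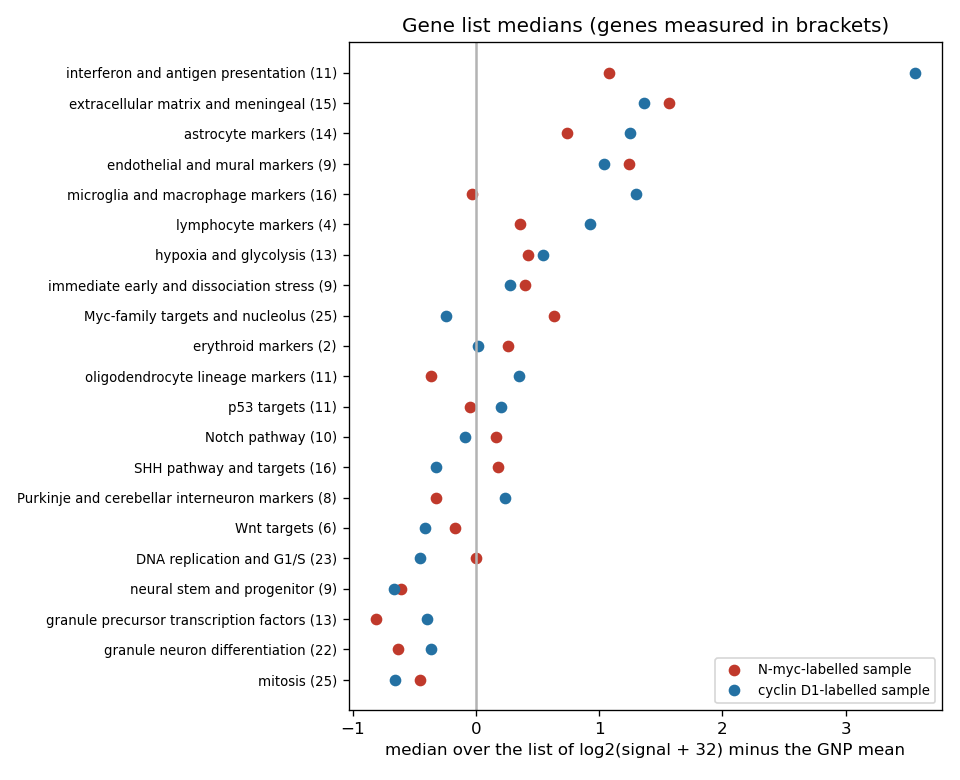
Median difference in log2(signal + 32) from the GNP mean over each gene list, for each infected sample, with the number of genes measured in brackets. The interferon and antigen presentation list has medians of 1.08 (N-myc label) and 3.56 (cyclin D1 label), and the mitosis list -0.45 and -0.66.

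The N-myc comparison asks what differed between the N-myc-labelled sample and GNPs. Most called probe sets, 218 of 272, were lower, and 54 were higher. Cntn2, an adhesion molecule of granule neurons, fell by 3.73 (adjusted p = 0.0251), while its 3 probe sets on array B read -1.01 to -1.55 and did not pass. Cnp, of the oligodendrocyte list, fell by 2.60 (adjusted p = 0.0382), and of its other probe sets 1 read -3.41 and passed (adjusted p = 0.0251) while 1 read -0.85 and did not (adjusted p = 0.179). Gabrb1, a GABA receptor subunit gene, fell by 2.97 on array A (adjusted p = 0.0251) and read 0.26 on array B. Dll3, a Notch ligand gene, rose by 1.94 (adjusted p = 0.041) and the hexokinase gene Hk2 by 1.72 (adjusted p = 0.0488). The median of Myc-family targets was 0.63, above all 10000 matched random lists, against -0.24 in the cyclin D1-labelled sample (percentile 10), with 0 of its 25 genes past the threshold in either. That rank ignores correlation between genes, and the matrix, endothelial, interferon and astrocyte lists, the last of which did not pass camera, also lay above all random lists in the N-myc-labelled sample.

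At an unadjusted p under the limit 4924 probe sets passed in the N-myc comparison. The count at the adjusted threshold was 0 without the filter, 2 with both array types in 1 fit, 482 with median centring, 513 with an offset of 100, 566 with adjustment within each array type, 701 with quantile normalization, 1391 with the stricter filter and 1915 with an intensity trend. Without GNP replicates 1, 2 and 3 it was 3, 4 and 734, with 3, 3 and 197 of them higher.

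The cyclin D1 comparison asks the same of the cyclin D1-labelled sample. Of the 11 genes of the interferon and antigen presentation list, 8 rose past the threshold, 2 of them (Ifitm3 and Irf1) interferon genes. Cd74, the MHC class II invariant chain, rose by 5.82 (adjusted p = 0.0149), H2-Aa by 5.81 (adjusted p = 0.0422), H2-K1 by 5.04 (adjusted p = 0.0297, with 1 of its 4 probe sets not past the threshold) and B2m by 3.56 (adjusted p = 0.0149). Lyz2, a macrophage gene, rose by 3.11 (adjusted p = 0.0226), and Sp5, of the Wnt target list, fell by 3.51 (adjusted p = 0.0149). In total 260 probe sets passed, 124 higher and 136 lower, and 4459 at an unadjusted p under the limit. The count was 0 without the filter, 5 with both array types in 1 fit, 396 with quantile normalization, 433 with adjustment within each array type, 476 with an offset of 100, 1299 with the stricter filter and 1653 with an intensity trend. Without GNP replicates 1, 2 and 3 it was 58, 123 and 527, with 45, 80 and 247 of them higher.

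The infected samples were also set against each other, with no test, since each was measured once. Genes of antigen presentation were among the largest differences. H2-Aa read 38.2 in the N-myc-labelled and 10088 in the cyclin D1-labelled sample against 177 ± 136 (SD, n = 3) in GNPs. Its probe set on array B read 831.7 and 6811 against 311 ± 116 (SD, n = 3), so the N-myc-labelled sample was below GNPs with 1 probe set and above them with the other. Cd74 read 314.5 and 11947, H2-K1 1040 and 22860, and Iigp1, an interferon-induced GTPase gene, 308.8 and 7023. Ttr, known from the choroid plexus, read 324.8 and 11649. Ipcef1, Jakmip1 and Gabrb1 were also higher in the cyclin D1-labelled sample. In the other direction Pcdh18 read 700.2 and 20.8, Dcps 639.8 and 21.2, and Wdr31 347.2 and 9.7. Grik1, Krt78, Bcl6, Ivl and Ccdc9 were likewise higher in the N-myc-labelled sample.

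By the size rule 346 of 12070 genes differed between the infected samples, 133 higher in the N-myc-labelled and 213 in the cyclin D1-labelled sample. Differences of that size, without the range condition, were seen in 366 genes here and in 126, 166 and 206 genes between pairs of GNP replicates. The count was 51 with the stricter filter (2 higher in the N-myc-labelled sample), 131 with an offset of 100 (34), 832 without the filter (434, so the majority turned) and 1605 with a log2 difference of at least 1.

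Agreement of the infected samples was measured across genes, which are not independent replicates. Their differences from GNPs had r = 0.44, where simulated unchanged groups sharing the same controls gave a mean of 0.25 and at most 0.284. The covariance was 0.245 against a simulated 0.0342. Of the called probe sets 35 were higher in both and 28 lower in both, which shared controls alone would also favour and which was not simulated.

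Genes were also grouped by chromosome, because mouse medulloblastomas can gain or lose whole chromosomes. The 438 genes on chromosome 13 had a median difference from GNPs of -0.37 in the N-myc-labelled and -0.29 in the cyclin D1-labelled sample, below all 10000 matched random lists in both. The 604 genes on chromosome 6 had medians of 0.22 and 0.20, above all random lists, a rank that ignores correlation between genes. The rank alone does not single out these chromosomes, as chromosome 11 was also below all random lists in the N-myc-labelled sample, with a median of -0.06. On chromosome 13, 70.8% of genes were lower in each infected sample. Medians of the other chromosomes lay between -0.06 and 0.11 in the N-myc-labelled and between -0.08 and 0.03 in the cyclin D1-labelled sample. With median centring the chromosome 6 medians were 0.08 and 0.12, and without the filter the chromosome 13 medians were -0.16 and -0.18.

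**Figure D4:**
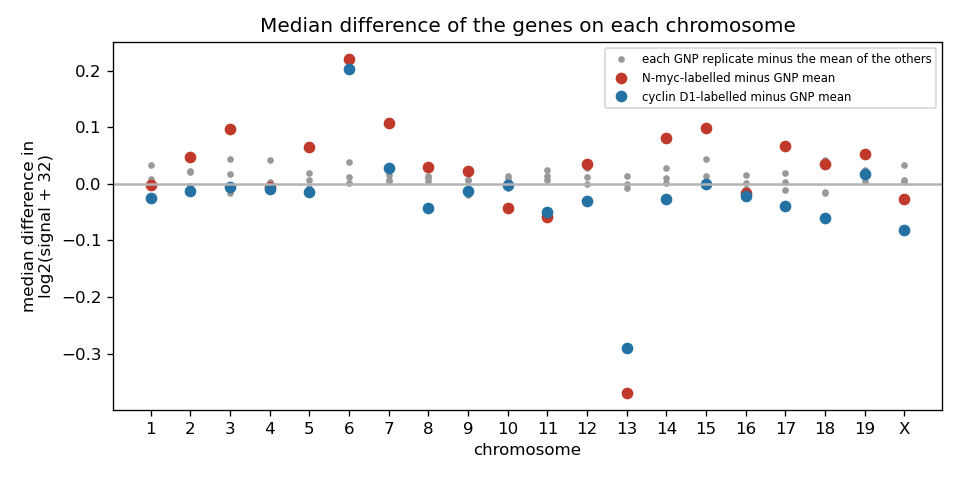
Median difference in log2(signal + 32) of the genes on each chromosome, for each infected sample minus the GNP mean, with each GNP replicate minus the mean of the others in grey. Chromosome 13 lies at -0.37 and -0.29, and chromosome 6 at 0.22 and 0.20.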

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

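The 3 tests of the Mycn probe set and both tests on a lower share of granule cells were chosen only after the results were seen.

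Probe sets without a gene name are counted in the state comparison but stand outside the named genes and gene lists, and 3 of them on array A gave a signal far above GNPs. In the N-myc-labelled sample they read 40940, 27988 and 6627, and in the cyclin D1-labelled sample 24313, 24425 and 4223, against at most 203, 26.2 and 18.8 in a GNP replicate (adjusted p = 0.0262, 0.000475 and 0.00103).

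The first pattern to weigh is the jump of the Mycn probe set dimmest in GNPs, in both infected samples. Greater activity of the cells' own Mycn gene is argued against by the brightest Mycn probe set, whose log2 difference was -0.19. That the cyclin D1-labelled sample carried the N-myc construct stays open: the probe set from the same GenBank record read 269.9 there, within the GNP replicates, but the 1020 of the N-myc-labelled sample did not pass the test either (log2 1.61, adjusted p = 0.0626). Sequence shared by both retroviral vectors stays open too: of the 4 probe sets of array A that went from under 300 in every GNP replicate to over 4000 in both infected samples, 3 were unnamed, against 6.87% of the array. The test of that share (one-sided exact hypergeometric p = 0.00123) and its limits were set after these probe sets had been seen, so it decides nothing, and the vector sequences were not used here.

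For some genes the infected samples lay on opposite sides of GNPs, given here as N-myc-labelled minus cyclin D1-labelled in log2, and these differences were not tested, with 1 sample each. Higher in the N-myc-labelled sample were Ccnd1 with its brightest probe set (1.25), Pcdh18 (3.79), Dcps (3.66), Grik1 (3.28), Krt78 (3.25), Bcl6 (3.17), Ivl (3.06), Ccdc9 (3.06) and Axin2 (0.74). Higher in the cyclin D1-labelled sample were H2-Aa (-7.17), Jakmip1 (-4.21) and Gabrb1 (-4.06). In each of these except Ccnd1 and Axin2, the lower of the infected samples read under the median of its array, so the size depends on the offset and the processing (-8.01 to -6.20 for H2-Aa and -5.35 to -2.95 for Gabrb1 over the alternatives). With the array B probe sets of H2-Aa (-2.99) and Gabrb1 (-0.71), both infected samples were above the GNP mean.

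The second pattern is the shift of chromosomes 6 and 13 in both infected samples. Spread like that between GNP replicates is argued against, because a replicate set against the others moved these medians by at most 0.0393. Spread between brain samples was not measured, and medians of other chromosomes there reached 0.11 (N-myc label) and -0.08 (cyclin D1 label). A few strongly changed genes would hardly move a median over so many genes, so the outcome of their test was largely fixed in advance. Without the 10% most changed genes in each direction the smallest mean shift was still 0.22. A copy number change along the whole chromosome may account for it, as each of 4 consecutive parts of both chromosomes moved the same way, by at least 0.16 in both samples. No DNA measurement was used here, and a shared origin of the infected cells remains untested.

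The third pattern is the higher matrix, vascular and antigen presentation lists, for which a lower share of granule cells would raise the markers of every other cell type alike. Endothelial minus oligodendrocyte medians differed by 1.61 and 0.69, but the bootstrap 95% intervals, -0.21 to 2.42 and -0.13 to 1.40, decided nothing. A second test, run after that one, set the 35 measured genes of the 3 lists against 49 of 4 other cell type lists. It gave 1.33 (0.71 to 1.75) and 0.59 (0.12 to 1.76), but as the 3 lists were picked for being higher it decided nothing either. A scaling difference between whole arrays was examined with the median infected minus GNP difference of the kept array A probe sets. It was -0.02, which the shared trimmed mean largely fixed in advance, -0.05 after quantile normalization and -0.20 under median centring. The list medians were at least 1.03 after quantile normalization and at least 0.81 over the alternatives run for the lists. Shifts of these sizes are argued against as the source of the higher lists, while a larger one was not tested. The columns already shared a trimmed mean, so quantile normalization had little left to change. A lower share of granule cells, a change in the cell types that rose, and the purification of GNPs against whole tissue, stay open, since the design confounds them with the states.

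The state comparison called 78 probe sets, and the highest of the other splits of the 5 samples called 0. With 1 of 10 splits as large, the splits are too few for a share under 0.05.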

How the results depend on the processing

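Detection calls were not used here, so which dim probe sets lie above background is not known, and each infected group holds a single sample. Leaving out each infected sample for the gene lists was chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the groups share replicate number 1 alone. Under the stricter filter the erythroid list and many of the named genes gave no value, as their probe sets did not reach it. Leaving out a GNP replicate removed a few named genes in the same way. Leaving out either infected sample removed most of the named rises: Snhg11, Mgp, Ccl5, Bhlhe40, Plxnd1, Cnn2 and Cflar. It also removed the Mycn probe set dimmest in GNPs and list members such as Eng and S100a6, so these were not checked in that way. Where an infected sample was left out, the lone one is assumed to vary like the GNP replicates. The direction of a list is that of its test. For each value below the cause was not tested, apart from fewer or more probe sets tested and fewer samples.

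All 24 genes named in the state comparison kept their direction under every alternative that gave a value. They were named for having both infected samples beyond all GNP replicates, so no offset or left-out sample could turn them. Their calls held in 24 with an offset of 100, 23 with quantile normalization, 23 with median centring, 16 with an offset of 1, 15 with an intensity trend, 11 with both array types in 1 fit and 1 without the filter. Of the 78 called probe sets, 74 were called with quantile normalization, 70 with median centring, 47 with an intensity trend and 28 with the stricter filter. The jump of the Mycn probe set dimmest in GNPs passed in all 11 alternatives that gave a value (adjusted p 6.62e-06 to 0.0131), none of which left out an infected sample. The 16 differences between the infected samples kept their direction too, which neither the offset nor leaving out a GNP replicate could turn. The named genes of the N-myc and cyclin D1 comparisons kept theirs under each alternative run for them that gave a value. All calls of these named genes were lost without the filter and with both array types in 1 fit, and most were lost without GNP replicate 1 or 2. Other probe sets were not among these alternatives, and that of Gabrb1 on array B read 0.26 in the N-myc comparison, against -2.97. The matrix, interferon, endothelial and mitosis lists passed in all 12 alternatives with the preset correlation, and 0 lists passed with an estimated correlation.

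With an offset of 1 the state count was 37. The chromosome 13 medians were -0.39 (N-myc label) and -0.31 (cyclin D1 label), and the directions turned for the Purkinje list (median -0.11) and Grik1 (-0.14). With an offset of 100 the state, N-myc and cyclin D1 counts were 162, 513 and 476, and 131 genes differed between the infected samples. The chromosome 6 median of the N-myc-labelled sample was 0.20 and the chromosome 13 medians -0.34 and -0.27.

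Quantile normalization gave 701 and 396 probe sets in the N-myc and cyclin D1 comparisons, an agreement of r = 0.412, and chromosome 13 medians of -0.40 and -0.31. Median centring moved the median infected minus GNP difference of the kept array A probe sets to -0.20 from -0.02. Under it 482 probe sets passed in the N-myc comparison, the chromosome 6 medians were 0.08 and 0.12, those of chromosome 13 -0.50 and -0.37, and the Purkinje list turned (median -0.19). The astrocyte and lymphocyte lists gained a call (adjusted p = 0.0489 and 0.0492).

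Without the filter 4, 0 and 0 probe sets passed in the state, N-myc and cyclin D1 comparisons, and 832 genes differed between the infected samples. Agreement was 0.361, the chromosome 6 median 0.26 (N-myc label) and the chromosome 13 medians -0.16 and -0.18. The tests of the SHH (median -0.089), Notch (-0.12), Wnt (-0.073) and Purkinje (0.21) lists turned, and the lymphocyte list gained a call (adjusted p = 0.00743). With the stricter filter the counts were 443, 1391 and 1299, and 51 genes differed between the infected samples. Agreement was 0.505, both chromosome 6 medians 0.17, and the chromosome 13 medians -0.56 and -0.46. The Wnt list turned (-0.19) and the Notch list gained a call (adjusted p = 0.024).

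An intensity trend gave 499, 1915 and 1653 probe sets, both array types in 1 fit 36, 2 and 5, and adjustment within each array type 566 and 433 in the N-myc and cyclin D1 comparisons. A log2 difference of at least 1 was seen in 1605 genes between the infected samples. DNA replication lost its call with quantile normalization (adjusted p = 0.106), without the filter (0.0733) and with the stricter filter (0.0708).

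Other probe sets pointed the other way for Mycn (0.71, and 7.92 for the jump, whose size depends on the offset, against -0.19), Jakmip1 (0.23), Gabrb1 (0.61), Eif4e (0.017 and 0.24), Plk2 (-0.69), Msi1 (2.69), Nkd1 (0.22, 0.040 and 0.53), Ighm (-0.26) and Cd8a (-0.19).

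Over leaving out each sample the state count ran from 4 to 448. Over the GNP replicates the N-myc count ran from 3 to 734, the cyclin D1 count from 58 to 527 and agreement from 0.468 to 0.488. Unchanged groups sharing 2 controls gave a mean of 0.334 and at most 0.368 in 100 simulations, against 0.25 with 3, so the higher agreement without a replicate does not show more shared change. The chromosome 6 median of the cyclin D1-labelled sample ran from 0.21 to 0.24, and those of chromosome 13 from -0.39 to -0.37 (N-myc label) and -0.33 to -0.31 (cyclin D1 label).

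The ranges over leaving out each sample follow for each direction that turned, in log2. Without GNP replicate 1 or 2 this was so for Grik1 (-0.52 to 1.76), Ivl (-0.15 to 1.76) and the Purkinje list (-0.76 to 0.18), and without replicate 1 also for the erythroid list (-0.051 to 0.26) and Gzma (-0.12 to 0.69). Without replicate 3 it was so for Ipcef1 (-1.86 to 2.42). Without the N-myc-labelled sample Mycn turned (-0.38 to 0.011 with the brightest probe set, and -0.19 to 1.61 with that of the same GenBank record as the jump), as did Ccnd1 (-0.32 to 0.93), Jakmip1 (-2.42 to 1.79), Gabrb1 (-2.97 to 1.10), Bpgm (-0.33 to 0.070) and Cd8a (-0.095 to 0.39). So did the SHH (-0.32 to 0.18), Myc-family (-0.24 to 0.58), Notch (-0.087 to 0.17) and Purkinje lists. Without the cyclin D1-labelled sample Pcdh18 (-3.16 to 0.64), Dcps (-3.25 to 0.41), Krt78 (-2.43 to 0.82), Wdr31 (-1.46 to 0.28), Bcl6 (-2.0 to 1.16), Ccdc9 (-2.25 to 0.82), Axin2 (-0.60 to 0.14), Ipcef1 and Gzma turned, with the p53 (-0.068 to 0.20) and oligodendrocyte (-0.37 to 0.35) lists.

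DNA replication lost its call without GNP replicate 1 (adjusted p = 0.0807). Calls were gained by astrocyte markers without GNP replicate 1 (0.00774), GNP replicate 2 (0.0263) or the N-myc-labelled sample (0.0265), and by lymphocyte markers without GNP replicate 3 (0.049). Immediate early genes gained one without the N-myc-labelled sample (0.0369), and the Myc-family (0.00313) and Purkinje (0.024, lower) lists without the cyclin D1-labelled sample.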

Other observations

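Some genes named by the rule have not been described. Pvalb, Slc6a5, Ugt8a, Plk2, Cd79a and the called Ccnd2 probe set read under the median of their arrays in all samples of a state, so their sizes depend on the offset. Among interneuron and Purkinje markers, Pvalb, which encodes the calcium buffer parvalbumin, rose in the cyclin D1-labelled sample by 2.89 in log2 (adjusted p = 0.0265) and had a value of 1.74 in the N-myc-labelled one. Slc6a5, a glycine transporter gene, had values of -2.35 in the N-myc-labelled and -1.03 in the cyclin D1-labelled sample and did not pass. Clu, which encodes clusterin, rose in both single-sample comparisons, by 2.02 (adjusted p = 0.0488) and 3.28 (adjusted p = 0.0265), with 1 and 2 of its 3 probe sets past the threshold. Among oligodendrocyte lineage genes Ugt8a, an enzyme gene of myelin lipid synthesis, fell in the cyclin D1-labelled sample by 2.30 (adjusted p = 0.0372), while the transcription factor gene Olig1 had a value of 1.41 in the state comparison and did not pass.

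Other named members had these log2 values in the state comparison and did not pass there with the probe set that stood for the gene. In the SHH list they were Igf2 (0.94), Gas1 (-1.15) and Ccnd2 (-0.83), of which Gas1 lies on chromosome 13 and Ccnd2 on chromosome 6. Of the other 6 Ccnd2 probe sets, 1 fell (-2.11, adjusted p = 0.0307) and 5 read -0.20 to -1.11 and did not pass. In the Notch and Wnt lists Jag1 (1.23) and Notum (0.84) were higher. Fabp7, a gene of radial glia, was lower (-1.38). Among p53 targets Plk2 (1.91) was higher and Trp53inp1 (-0.92) lower. The immediate early gene Egr1 (1.18), the B cell gene Cd79a (1.55), the interferon regulator gene Irf7 (1.36), the complement gene C1qa (2.34) and the hypoxia gene Car9 (0.98) were higher in value.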
